A study of Homo sapiens with 6 samples.

How the data were processed

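RNA was sequenced from 6 libraries of SKOV3, an established human ovarian cancer cell line: 3 control libraries and 3 libraries of cells with an shRNA against CPT1A. The labels describe the controls as wild type in normal culture and mention no control hairpin, and the deposited columns of the shRNA libraries carry the tag sh2, which the labels do not explain, so that which hairpin was used is not known and the effect of the hairpin's target and that of carrying a hairpin were not separated by the design. Per the labels, total RNA was taken by TRIzol or a column kit. They name both poly(A) selection and rRNA removal without saying which was used, and random priming was followed by 13 PCR cycles. The strand of the reads is not stated, so reads from overlapping genes on opposite strands were not separable here.

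The deposited table gives for each of 57905 genes a raw count and an FPKM value per library. The counts are whole-number reads per gene as deposited by the authors, whose notes name cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq2 without giving their roles. The deposited FPKM values were made by the authors as the count per kilobase of exonic length, relative to the library's summed counts; this formula gave 100% of the values in each library within 0.0051. The notes name the mouse build mm8, whereas the table holds human Ensembl identifiers; 90.4% of them are in GENCODE 29, but of those genes only 365 have the same start as on GRCh38. Coordinates are therefore given as in the authors' table, and the build is not given in the sources used here. No library was pooled or left out. There were 28290 genes with no count in any library.

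Groups were compared with edgeR 4.0.16 in R 4.3.3: raw counts of the 12784 genes with at least 1 FPKM in at least 3 of the 6 libraries, trimmed-mean (TMM) scaling, and quasi-likelihood F tests with an abundance trend. Benjamini-Hochberg adjustment ran over the genes tested, and a gene was called at an adjusted p under 0.05. The plan had set limma on log2(FPKM + 1) for a file without counts and edgeR for one with counts; the latter applied, and the former is among the alternatives. Log2 changes are fitted values, and their standard errors (SE) are those of the difference between group means of log2 CPM with a prior count of 2. Shares of counts were compared by an exact two-sided permutation test, for which 3 against 3 allows no p below 0.1, and all other p-values were adjusted values from models across genes unless a test is named. Intervals for RPPH1 and MIR590 are exact 95% binomial intervals of the ratio of counts relative to total counts. They cover counting error only, since PCR copies are not independent molecules. Variation between libraries of a group exceeded counting error, with a chi-square per degree of freedom of 6.68 to 38.1.

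The test, the filter, the gene lists and the rule for naming genes were fixed before the data were examined. The rule named CPT1A, CPT1B, CPT1C, CPT2 and MFF. It also named the 12 genes with the largest increase and the 12 with the largest decrease among called genes with a symbol, separated groups and at least 5 FPKM in the higher group, and up to 4 called members with the smallest p in each list. Clone-based names were not counted as symbols. ERN1 was named after its values were seen, as were genes overlapping a named gene. The 37 lists, written from general knowledge, covered the carnitine shuttle and beta-oxidation, fatty acid synthesis, cholesterol synthesis, lipid droplets, PPAR targets, complex I, complexes II to V, mitochondrially encoded genes, the citric acid cycle, succinylation enzymes, fission and fusion, contacts of mitochondria with the endoplasmic reticulum, the unfolded protein response, the ATF4 stress response, glycolysis, hypoxia, ovarian stemness, Notch, Wnt and Hedgehog, epithelial genes, mesenchymal and matrix genes, G1/S, G2/M, p53 targets, apoptosis, interferon-stimulated genes, NF-kB, antigen presentation, NRF2 and ferroptosis, autophagy, YAP and TAZ targets, calcium handling, immediate early and heat shock genes, ribosomal proteins, histones, and markers of fibroblasts, endothelium and immune cells. The 34 lists with at least 5 tested members were tested against other genes with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 and again with an estimated correlation. The estimated version was stricter even where the correlations were nearly equal. For cholesterol synthesis, with an estimate of 0.0113, the unadjusted camera p went from 7.47e-18 to 0.00104. A call lost with it therefore does not show that a list moved no more than other genes. Fry tested each list against no change, not against other genes. Adjustment ran over the lists. Of these, 10 were called with the preset correlation.

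The procedure was tested on simulated data with the depths and dispersions of these libraries. It recovered 40% of 50 genes changed 1.5-fold, 84% of 50 changed 2-fold and 96% of those changed 4-fold or 8-fold, with 8 false calls. With no gene changed it called 0 genes and 0 lists. Genes were simulated independently of each other, so this does not bear on list calls among correlated genes. Only 50 of 12784 genes were changed at each fold, whereas 3509 were called in the data. The adjustment is stricter where fewer genes change, so these shares need not hold for the data.

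Alternatives were limma on log2 FPKM with pseudocounts of 1, 0.1 or 0.5, other filters and scalings, other variance models, a replicate block, leaving out each library, stricter thresholds, DESeq2 1.42.0 and leaving out mitochondrially encoded genes. Added after seeing the data were total-count scaling, filterByExpr, offsets that removed each library's trend with exonic length and GC content (a lowess curve for each), protein-coding genes only, and leaving out RPPH1 or the genes with a 7-base 3' UTR site. The 3' UTR of at least 50 bases of 10683 tested genes, from GENCODE 29, was searched for all 7-base words present in at least 30 of these genes, 16324 words. Each word was scored by the mean log2 change of the genes that hold it, after regression on 3' UTR length and GC content, gene GC content, exonic length and expression, in standard errors under random assignment. The score was compared with 200 permutations of the residuals. Gene Ontology terms with 10 to 500 tested genes, as the authors annotated the genes, were tested with camera.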

Results

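RNA sequencing was used to ask how lowering CPT1A, the outer-membrane enzyme that commits long-chain fatty acids to import into mitochondria, changed gene expression in SKOV3, an established human ovarian cancer cell line. The series title places the work in the study of CPT1A-dependent succinylation of the fission factor MFF, of stem-like ovarian cancer cells and of contacts between mitochondria and the endoplasmic reticulum. There were 6 libraries: 3 from control cells, labelled wild type in normal culture, and 3 from cells given an shRNA against CPT1A. The labels call the 3 libraries of each group biological replicates. Their titles do not say whether the shRNA was introduced separately for each of the 3 libraries. The p-values therefore measure spread between libraries, which need not be spread between independent knockdowns. The libraries held 15740143 to 22271565 counts over annotated genes, and 12784 genes passed the minimum of 1 FPKM in at least 3 libraries. The first principal component of log2 CPM carried 61.2% of the variance and separated the groups. Control replicate 2 lay at -17.7 on it, nearer to the shRNA libraries (26.5 to 32.9) than the other control libraries at -36.1 and -34.6.

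CPT1A transcripts were at 7.59 ± 0.77 FPKM in control libraries and 2.04 ± 0.11 FPKM in shRNA libraries (mean ± SD, n = 3 each), a fitted decrease of 3.91-fold. All 3 shRNA libraries lay below all 3 control libraries. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. In edgeR's quasi-likelihood test the log2 change was -1.97 ± 0.09 (SE), with a Benjamini-Hochberg adjusted p = 3.3e-06. CPT1A (ENSG00000110090) lies on the minus strand of chromosome 11 from 68522088 to 68611878 in the authors' table. The related carnitine palmitoyltransferases did not pass the test: CPT2, of the inner membrane, had 7.78 ± 0.45 FPKM in control and 9.57 ± 0.70 FPKM in shRNA libraries (edgeR adjusted p = 0.223), and CPT1B had 1.82 ± 0.30 and 1.66 ± 0.38 FPKM (edgeR adjusted p = 0.506). The neuronal form CPT1C, at 0.32 ± 0.06 and 0.23 ± 0.01 FPKM, was below the expression minimum. MFF, the mitochondrial fission factor that recruits the fission GTPase DNM1L, had 21.1 ± 1.5 and 20.4 ± 1.2 FPKM, a log2 change of -0.11 ± 0.07 that did not pass (edgeR adjusted p = 0.465).

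**Figure D1:**
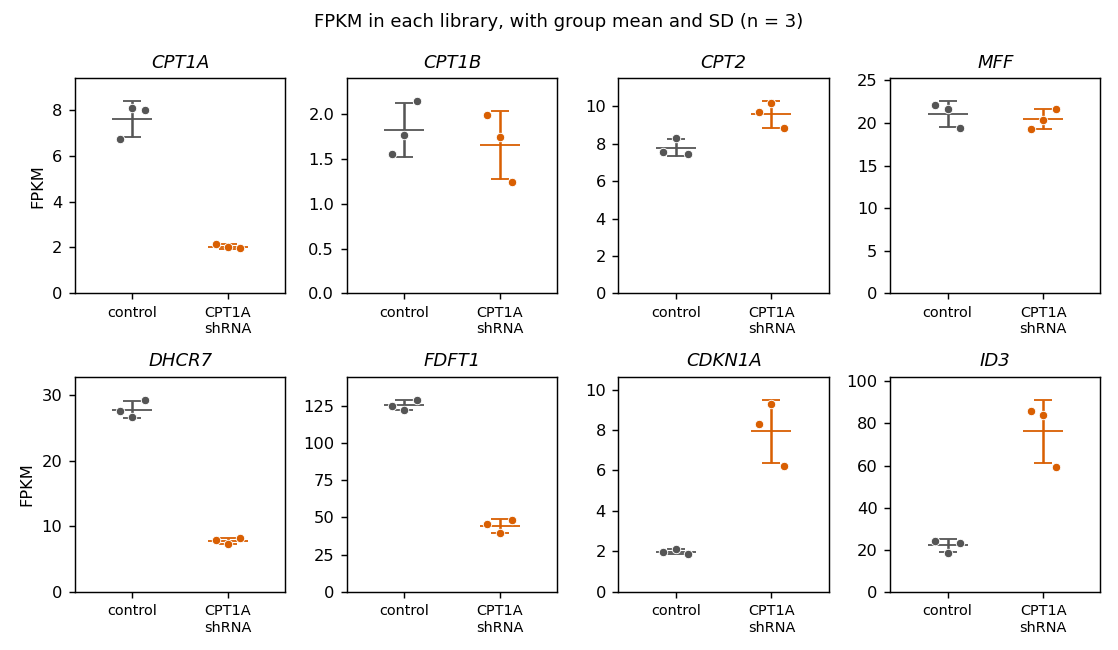
Transcript level (vertical axes, FPKM, starting at 0) of 8 genes in the 3 control and 3 CPT1A shRNA libraries; points are libraries, horizontal bars group means and error bars the SD. CPT1A, DHCR7 and FDFT1 were lower and CDKN1A and ID3 higher in every shRNA library, while the CPT1B and MFF values of the groups overlapped.

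Of the 12784 tested genes, 3509 differed between the groups at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, 1762 higher and 1747 lower in the shRNA libraries. A change of at least 2-fold was reached by 306 of the higher and 376 of the lower genes. In 3412 of the 3509 genes the 3 libraries of one group all lay above the 3 of the other; among all tested genes this held for 42.2%, against 10% by chance. The share of called genes that were higher was 50.2%, and it was 50.7% with median-ratio size factors and 61.8% with total counts alone. With limma, a change of both test and scaling, it was 53.4% on quantile-normalized values, 60.5% on log2(FPKM + 1) and 73.2% on FPKM rescaled to a common sum, a scaling under which the median log2 change of all genes was 0.15 against -0.01. The count of changed genes fell to 1882 without control replicate 1 and to 2060 without shRNA replicate 2.

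The largest increase was in the gene that the authors' table names RPPH1 (ENSG00000259001), after the RNA component of ribonuclease P, with 4, 3 and 4 counts in the control libraries and 1292, 1149 and 1278 counts in the shRNA libraries. Relative to total counts this was a 379-fold difference, with a 95% exact counting interval of 211 to 759. The gene model behind RPPH1 in the authors' table, chromosome 14 from 20811207 to 20811844, was 638 bases long, against 333 bases for this RNA in GENCODE 29, where the counted identifier is typed as antisense and has no symbol of its own. It overlapped the divergent gene PARP2. Among the other genes with the largest increases were the cell cycle inhibitor CDKN1A (1.97 ± 0.12 to 7.94 ± 1.55 FPKM, 3.82-fold), the transcriptional inhibitors ID3 (21.99 ± 2.95 to 76.3 ± 14.9 FPKM) and ID2 (3.16-fold), and the histone methyltransferase KMT2D (4.19 ± 0.90 to 13.4 ± 1.7 FPKM, 3.06-fold). SOCS7, of the suppressor of cytokine signalling family, rose 4.38-fold and SMCR8 4.04-fold. KIAA0754 rose 8.27-fold, but it lies inside MACF1 on the same strand, whose own change was 0.21 on the log2 scale (edgeR adjusted p = 0.302). The non-coding genes SH3RF3-AS1 (4.36-fold), SNORD17 (4.35-fold, within SNX5), LINC00620 (3.16-fold) and MIR590 (3.28-fold, within EIF4H) completed the 12. MIR590 had 17 counts over the control libraries and 53 over the shRNA libraries, and its call was lost without control replicate 1 (edgeR adjusted p = 0.0823) and without shRNA replicate 1 (edgeR adjusted p = 0.0556), within a range of 9.01e-07 to 0.0823 over 26 alternatives. For the remaining 11 genes the edgeR adjusted p ranged from 1.9e-10 (RPPH1) to 0.000406 (SMCR8).

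The largest decreases began with MMP7, the secreted protease matrilysin, at 108.4 ± 10.3 FPKM in control and 14.6 ± 9.6 FPKM in shRNA libraries (7.80-fold, edgeR adjusted p = 6.33e-05). MMP7 was at 25.6 FPKM in shRNA replicate 1 and at 9.96 and 8.18 FPKM in the others, and without shRNA replicate 1 its log2 change was -3.65 in place of -2.96. C1orf233 (5.44-fold), CYSTM1 (5.30-fold), C1orf122 (5.26-fold) and the enamel protein gene AMTN (5.08-fold) followed. VTA1, a cofactor of endosomal sorting, fell 4.61-fold, KIAA1522 4.29-fold and CDC42SE2 4.07-fold. COL4A1, a collagen of basement membranes, fell from 34.8 ± 5.7 to 8.78 ± 0.81 FPKM, and PSMA3, a subunit of the proteasome core, from 40.0 ± 2.0 to 10.5 ± 1.1 FPKM. ACAT2, the cytosolic thiolase at the head of the mevalonate pathway, fell from 38.6 ± 1.0 to 10.2 ± 1.4 FPKM. The cancer-testis gene SPANXB2 fell 3.96-fold, but it has near-identical copies among which reads can be split, and without control replicate 1 its edgeR adjusted p was 0.0525, the highest of a range from 1.61e-07 over 26 alternatives. In 8 of these 12 genes, and in CPT1A itself, the annotated 3' UTR held the 7-base sequence ATGTCCA or TGTCCAA. These were the lowest-scoring of 16324 words, picked from the fold changes of the same genes, so the shares that follow describe that choice and do not test it. Such a site was present in 352 of 1503 lower genes with a searched 3' UTR (23.4%), 247 of 1585 higher genes (15.6%) and 1154 of 7595 genes without a call (15.2%).

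**Figure D2:**
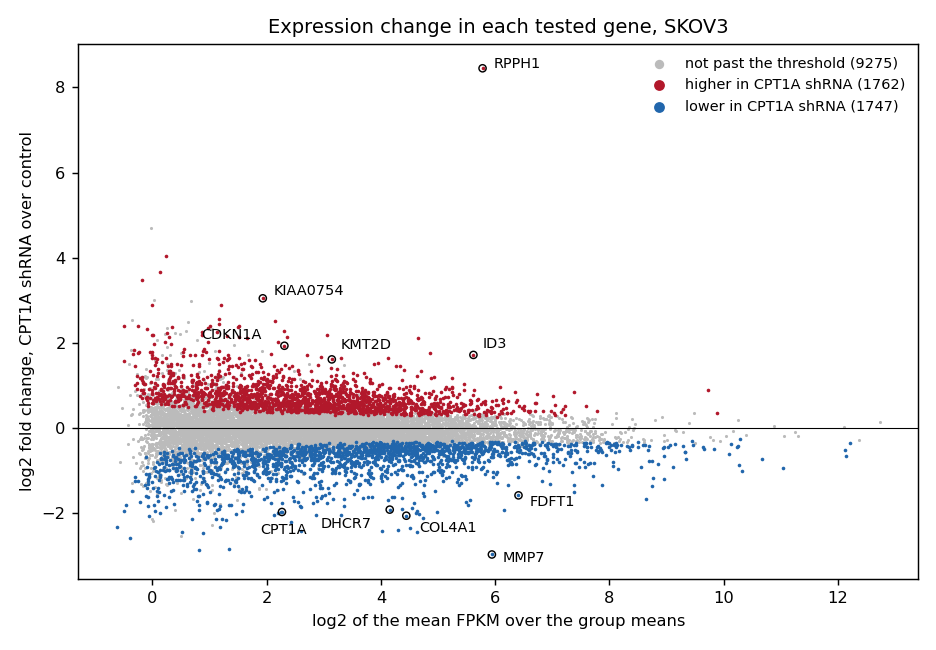
Log2 fold change of CPT1A shRNA over control (vertical axis) against the log2 of the mean FPKM of both groups (horizontal axis) for the 12784 tested genes; red points are the 1762 genes called higher, blue points the 1747 called lower and grey points the rest. RPPH1 stands alone at a log2 change of 8.45, and CPT1A lies at -1.97.

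Of 23 measured cholesterol synthesis genes 19 were lower and none higher, with a median log2 change of -0.85, and 20 were lower when adjusted over the list alone. DHCR7, the reductase of the last step to cholesterol, fell from 27.8 ± 1.4 to 7.78 ± 0.44 FPKM (3.76-fold), and the squalene synthase FDFT1 from 125.6 ± 3.5 to 44.3 ± 4.5 FPKM (2.98-fold). HSD17B7 fell 2.74-fold and the mevalonate kinase MVK 2.49-fold, although MVK overlaps MMAB, which also fell (log2 change -0.92). The list was lower than other genes by camera with the preset correlation (adjusted p = 2.54e-16), and it was the only list that kept its call with an estimated correlation (adjusted p = 0.0354). Among fatty acid synthesis and desaturation genes, 6 of 19 were lower and 2 higher, the same counts as when adjusted over the list alone. The desaturase SCD fell from 61.4 ± 7.8 to 28.2 ± 2.3 FPKM, SREBF1, which encodes a regulator of lipid synthesis, fell 1.88-fold and FADS2 1.62-fold, while the acetyl-CoA carboxylase ACACB rose 2.19-fold. FADS2 overlaps FADS1 on the other strand, which also fell (log2 change -0.31), and FEN1 on the same strand, which was not called (log2 change -0.07). That list as a whole was not apart from other genes (camera adjusted p = 0.375). Of 17 lipid droplet and triglyceride genes 4 were lower and 2 higher (4 and 3 adjusted over the list alone), with DGAT2 rising 1.82-fold and the lipase PNPLA2 falling 1.69-fold (camera adjusted p = 0.925). Of 11 PPAR targets 2 were lower and 2 higher (2 and 3 adjusted over the list alone); TXNIP rose 1.88-fold and FABP3 fell 2.15-fold (camera adjusted p = 0.757; median log2 change 0.03, mean -0.11). CPT1A is in this list and was the other lower gene, with the lowest log2 change.

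In the carnitine shuttle and beta-oxidation list, 5 of 29 genes were lower and 1 higher, with the same counts when adjusted over the list alone. Besides CPT1A, the acyl-CoA synthetase ACSL3 fell 1.66-fold, and the list did not stand apart (camera adjusted p = 0.54). In complex I 8 of 38 genes were lower and 1 higher (7 and 1 adjusted over the list alone), with a median log2 change of -0.25; NDUFS3 fell 1.74-fold and NDUFS1 rose 1.59-fold. NDUFS3 overlaps PTPMT1 on the same strand, which also fell (log2 change -0.87). On the other strand it overlaps KBTBD4, which rose (log2 change 0.74), and CELF1, which was not called (log2 change -0.08). In complexes II to V 12 of 38 were lower and none higher (12 and 0 adjusted over the list alone), with a median of -0.25; UQCRB fell 1.47-fold and ATP5O 1.43-fold. Both lists were called lower by camera with the preset correlation (adjusted p = 0.0254 and 0.00336) and neither with an estimated one (adjusted p = 0.822 for both). Their estimated correlations, 0.451 and 0.659, were far above the preset 0.01. Complex I also lost its call without control replicate 1 (adjusted p = 0.136), without control replicate 3 (adjusted p = 0.107) and without shRNA replicate 1 (adjusted p = 0.0521), and both lists lost it once the length and GC trends of the libraries were removed (adjusted p = 0.141 and 0.0909). Of the 15 mitochondrially encoded genes 3 were lower and 1 higher (4 and 2 adjusted over the list alone; camera adjusted p = 0.818), and their share of all counts was 3.91% ± 0.08 in control and 4.01% ± 0.14 in shRNA libraries (exact permutation p = 0.4). The 10 most abundant genes took 6.34% ± 0.28 and 5.64% ± 0.15 of the counts (exact permutation p = 0.1, the smallest possible).

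Enzymes that make or remove succinyl groups moved in both directions: 4 of 12 were higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.701). The lower genes were CPT1A itself, which is in this list, and SUCLG2. SUCLG2, a subunit of the succinyl-CoA ligase, fell 2.21-fold, and DLST, of the oxoglutarate dehydrogenase complex, rose 1.38-fold. Of 22 citric acid cycle genes 3 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.925). Of 20 fission and fusion genes 4 were higher and 1 lower (4 and 3 adjusted over the list alone), with SPIRE1 rising 1.84-fold and the fission adaptor MIEF1 1.57-fold. This list did not stand apart (camera adjusted p = 0.925; median log2 change -0.01, mean 0.02). Of 30 genes of contacts between mitochondria and the endoplasmic reticulum 6 were higher and 1 lower, also when adjusted over the list alone. The calcium channel gene ITPR3 rose from 23.2 ± 3.7 to 46.3 ± 6.9 FPKM and the tether RMDN3 1.57-fold (camera adjusted p = 0.375). Of 27 calcium handling genes 4 were higher and 2 lower, also when adjusted over the list alone; the calcium pump gene ATP2B4 rose 2.11-fold (camera adjusted p = 0.701).

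In the list of the unfolded protein response and chaperones of the endoplasmic reticulum 12 of 24 genes were lower and 2 higher (12 and 3 adjusted over the list alone). MANF fell from 56.8 ± 5.4 to 27.9 ± 0.9 FPKM, HSP90B1 1.65-fold and CALR 1.58-fold, whereas the stress sensor ERN1 rose 1.66-fold. The list did not pass (camera adjusted p = 0.0869), but it did in 6 of 28 alternatives. Among the 6 was fry, which does not compare the list with other genes (fry adjusted p = 0.0205). Over all 28 the adjusted p ranged from 0.0106 to 0.741. Of 23 genes of the ATF4 stress response 5 were lower and 4 higher (6 and 6 adjusted over the list alone), NUPR1 falling 3.05-fold and ASNS rising 1.82-fold (camera adjusted p = 0.999; median log2 change 0.18, mean -0.03). Cytosolic ribosomal protein genes were lower by small amounts: 34 of 52 were called lower and none higher (47 and 0 adjusted over the list alone), with a median log2 change of -0.38. RPL10 fell from 118.8 ± 16.5 to 73.3 ± 1.8 FPKM. These genes have many processed pseudogenes that can share their reads. The list was called lower by camera with the preset correlation (adjusted p = 1.95e-09) and not with an estimated one (adjusted p = 0.774). The estimate was 0.836 against the preset 0.01, so the camera adjusted p of 1.95e-09 overstates the evidence. The ribosomal protein share of counts was 4.70% and 4.73% in control replicates 1 and 3, 3.91% in control replicate 2 and 3.61% to 3.78% in the shRNA libraries.

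Of 26 ovarian stemness genes in the list 23 were matched to the data and 10 of them were tested. Among the 10 tested genes 3 were higher and 2 lower (4 and 3 adjusted over the list alone). KLF4, a transcription factor of the reprogramming set, rose from 2.31 ± 0.21 to 5.37 ± 0.31 FPKM. The pluripotency factor gene POU5F1, which has near-identical pseudogenes, fell from 5.68 ± 0.26 to 3.71 ± 0.18 FPKM. The list did not stand apart (camera adjusted p = 0.949; median log2 change -0.17, mean 0.04). Of 20 genes of the Notch, Wnt and Hedgehog pathways 6 were higher and 4 lower, also when adjusted over the list alone. CTNNB1, which encodes beta-catenin, fell from 41.9 ± 4.5 to 23.2 ± 1.6 FPKM and HES1 2.33-fold, while the Wnt receptor gene FZD7 rose 1.70-fold and NKD1 2.54-fold (camera adjusted p = 0.757). Epithelial genes were lower in 7 of 21 cases and higher in 2 (9 and 4 adjusted over the list alone), led by the keratins KRT19 (2.55-fold) and KRT7 (2.02-fold). Camera called this list lower (adjusted p = 0.0346), but not with an estimated correlation (adjusted p = 0.741). The call was lost in 12 of 28 alternatives, among them every limma fit. It was also lost without control replicate 3 (camera adjusted p = 0.107) or shRNA replicate 3 (camera adjusted p = 0.142). The same held without the genes with a 7-base 3' UTR site (camera adjusted p = 0.0772). Mesenchymal and matrix genes were lower in 12 of 24 cases and higher in 1, also when adjusted over the list alone, with a median log2 change of -0.40. Besides COL4A1, the collagenase MMP1 fell from 68.1 ± 4.8 to 21.6 ± 3.2 FPKM, COL1A2 3.84-fold and CTGF 2.21-fold (camera adjusted p = 8.42e-07; with an estimated correlation, adjusted p = 0.689). Of 21 YAP and TAZ targets 5 were higher and 5 lower (5 and 6 adjusted over the list alone), NUAK2 falling 2.37-fold and LATS2 rising 2.15-fold (camera adjusted p = 0.736).

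Of 23 NF-kB and inflammatory genes 12 were lower and none higher (13 and 0 adjusted over the list alone), with a median log2 change of -0.41. The chemokine CCL20 fell from 13.5 ± 1.1 to 4.46 ± 0.28 FPKM, the cytokine IL6 from 12.1 ± 0.6 to 4.76 ± 0.51 FPKM, IL32 2.33-fold and CXCL1 1.77-fold. Of 15 antigen presentation genes 10 were lower and none higher (11 and 0 adjusted over the list alone), with a median of -0.63. HLA-B, a gene whose reads can be split among close relatives, fell 2.25-fold. The immunoproteasome subunits PSMB8 and PSMB9, which overlap each other on opposite strands, fell 1.96-fold and 2.20-fold. Camera called both lists lower with the preset correlation (adjusted p = 3.77e-06 and 2.05e-05) and neither with an estimated one (adjusted p = 0.689 and 0.741). Of 24 interferon-stimulated genes 7 were lower and 2 higher (9 and 2 adjusted over the list alone), IFI6 falling 2.17-fold (camera adjusted p = 0.149). Without shRNA replicate 1 this list was called lower (adjusted p = 0.0081; range over 28 alternatives 0.00225 to 0.822).

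In the G2/M and mitosis list 12 of 41 genes were higher and 2 lower (18 and 2 adjusted over the list alone), with a median log2 change of 0.26. The spindle factor TPX2 rose from 104.1 ± 7.1 to 160.7 ± 8.1 FPKM, the mitotic kinase AURKA 1.47-fold and KIF20A 1.48-fold. It was the only list camera called higher (adjusted p = 0.00373; with an estimated correlation, adjusted p = 0.741). The broader Gene Ontology terms mitotic nuclear division (222 genes, median log2 change 0.04, camera adjusted p = 0.517) and cell division (273 genes, median 0.05, camera adjusted p = 0.547) did not pass. Of 41 G1/S and replication genes 5 were higher and 6 lower (6 and 6 adjusted over the list alone), PCNA falling 1.89-fold and FANCD2 rising 1.66-fold (camera adjusted p = 0.999; median log2 change -0.02, mean 0.01). Of 24 p53 targets 5 were higher and 1 lower (6 and 2 adjusted over the list alone), with SESN1 rising 1.94-fold beside CDKN1A (camera adjusted p = 0.375). Of 25 apoptosis regulators 6 were higher and 2 lower (6 and 3 adjusted over the list alone). APAF1, the scaffold of the apoptosome, rose from 1.18 ± 0.42 to 3.78 ± 0.29 FPKM and BCL2L11 1.84-fold, while BID fell 1.65-fold (camera adjusted p = 0.431).

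Glycolytic genes were lower in 8 of 22 cases and higher in none (9 and 2 adjusted over the list alone). The aldolase ALDOC fell from 12.8 ± 1.1 to 3.94 ± 0.61 FPKM, the glucose transporter SLC2A1 from 70.3 ± 0.8 to 37.95 ± 4.24 FPKM and PGK1 1.58-fold. Camera called the list lower (adjusted p = 0.0172), but not with an estimated correlation (adjusted p = 0.799). The call was lost in 9 of 28 alternatives, among them every limma fit. It was also lost without control replicate 3 (camera adjusted p = 0.107) and without the genes with a 7-base 3' UTR site (camera adjusted p = 0.0772). Of 17 hypoxia response genes 4 were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.962). Of 27 NRF2 and ferroptosis genes 8 were lower and 5 higher (9 and 5 adjusted over the list alone), KEAP1 falling 2.04-fold and SRXN1 rising 1.98-fold (camera adjusted p = 0.431). Of 32 autophagy and mitophagy genes 4 were higher and 4 lower (6 and 5 adjusted over the list alone), ATG7 rising 1.46-fold and OPTN falling 1.39-fold (camera adjusted p = 0.949). ATG7 overlaps VGLL4 on the other strand, which also rose (log2 change 0.69). Of 27 immediate early and heat shock genes 7 were higher and 6 lower (7 and 8 adjusted over the list alone). HSPB1 fell from 329.0 ± 57.7 to 137.5 ± 17.2 FPKM and KLF6 rose from 33.4 ± 5.5 to 65.6 ± 4.7 FPKM (camera adjusted p = 0.999; median log2 change -0.02, mean 0.05). Of 30 replication-dependent histone genes in the list 13 were matched to the data and 8 of them were tested. The lack of a match says nothing of the expression of the others. Among the 8 tested genes 1 was higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.736).

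**Figure D3:**
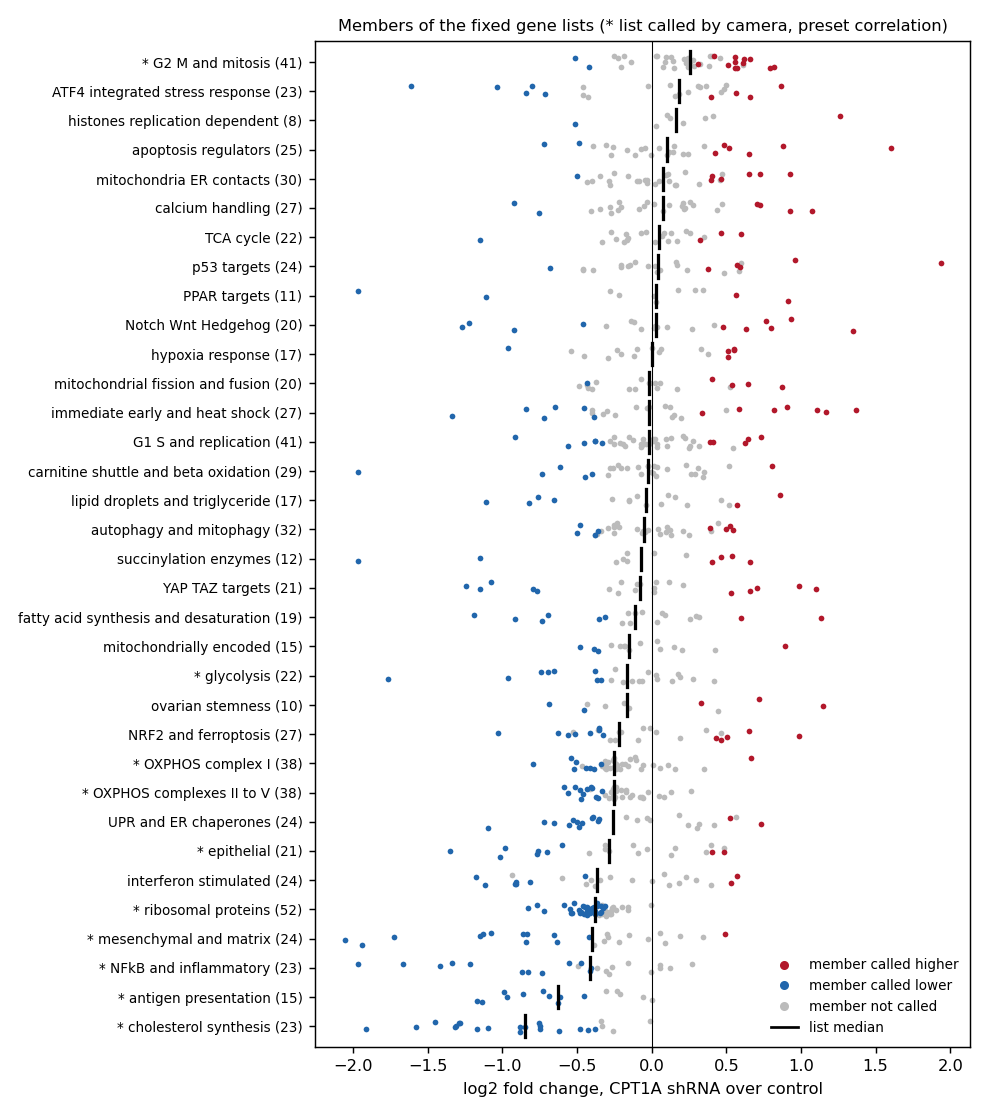
Log2 fold change of CPT1A shRNA over control (horizontal axis) for every tested member of the 34 lists with at least 5 tested members; red points were called higher, blue points lower, grey points neither, black bars are list medians, and an asterisk marks the 10 lists called by camera with the preset correlation. Cholesterol synthesis had the lowest median, -0.85, and G2/M and mitosis the highest, 0.26.

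Markers of other cell types were scarce. None of the immune marker genes and 1 of the 9 endothelial marker genes matched to the data (EGFL7, log2 change -0.33, edgeR adjusted p = 0.153) reached the expression minimum. Of the fibroblast markers 3 did and all 3 were lower, also when adjusted over the list alone: MFAP5 (3.19-fold), COL1A2 (3.84-fold) and FBLN1 (log2 change -0.49). The FBLN1 call was lost without control replicate 1 (edgeR adjusted p = 0.0728), shRNA replicate 2 (edgeR adjusted p = 0.0977) or shRNA replicate 3 (edgeR adjusted p = 0.0609), within a range of 2.98e-05 to 0.0977 over 27 alternatives. The fold changes also followed transcript length. Across genes, the log2 change correlated with exonic length at a Spearman rho of 0.25, with a median of -0.16 in the shortest of 4 equal groups of genes and 0.15 in the longest; genes are not independent replicates. The control libraries differed in this trend among themselves: the rank correlation of each library's deviation with length was -0.32, 0.07 and -0.31 in control replicates 1, 2 and 3 and 0.17 to 0.23 in the shRNA libraries. With 3 libraries per group and few genes changed, the self-test recovered 84% of simulated 2-fold changes and 40% of 1.5-fold changes. Smaller changes in uncalled genes were therefore not excluded.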

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

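Total-count scaling, filterByExpr, the length and GC offsets, protein-coding genes only, and leaving out RPPH1 or the genes with a 7-base site were tests chosen only after the result was seen. A gene or list called in neither fit was counted as kept whatever its sign.

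The decrease of CPT1A kept its direction and its call in all 25 alternatives that tested it, with log2 changes of -2.13 to -1.36 and adjusted p up to 0.000488. Of 152 named genes 124 kept direction and side of the threshold in every alternative run. The only reversal was MT-CO2, at a log2 change of 0.025 under quantile normalization (adjusted p = 0.738; range over its alternatives 1.69e-05 to 0.738); the cause was not tested. CPT2 was called higher in 2 alternatives and MFF lower in 1 (array weights, adjusted p = 0.029; range 0.029 to 0.797).

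With limma on FPKM rescaled to a common sum, a change of both test and scaling, 2676 genes were higher and 981 lower, with a median log2 change of 0.15; the deposited FPKM summed to 299578 to 317985 in control and 289145 to 293271 in shRNA libraries. With array weights 9613 genes were called, 5372 higher and 4241 lower; the weights fit did not converge and gave control replicate 1 a weight of 21.3, and the cause was not tested further. Stricter thresholds gave fewer genes by construction: 1889 (994 higher, 895 lower) at an adjusted p under 0.01, 682 (306 and 376) with a fold of at least 2, and 490 (221 and 269) by a test against a fold of 1.5. With a replicate block 3261 genes were called; the replicate numbers did not pair the libraries, with correlations of -0.07, 0.01 and -0.25. DESeq2 called 3775 genes and the length and GC offsets 5103.

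Leaving out 1 library gave 1882 to 5050 changed genes, 968 to 2539 higher and 914 to 2511 lower. The lowest count was without control replicate 1 and the highest without control replicate 2; without shRNA replicate 2 it was 2060. The cause was not tested.

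Of the 10 called lists, cholesterol synthesis kept its call in all 28 alternatives, with adjusted p up to 0.0354. With an estimated correlation 0 lists were called higher and 1 lower. The estimates for the lists that lost their call ran from 0.137 (epithelial genes) to 0.836 (ribosomal proteins). They were 0.154 for G2/M, 0.166 for NF-kB and 0.17 for mesenchymal and matrix genes. The estimated version was also stricter at a correlation near the preset, so the lost calls do not rest on the correlation alone. Fry, which does not compare a list with other genes, called 2 higher and 9 lower, but these were largely different lists. Of the 10 called lists 5 kept their call, and 6 uncalled lists gained one. G2/M, ribosomal proteins, complex I, complexes II to V and epithelial genes lost theirs. The 2 lists that fry called higher were p53 targets and apoptosis. Its gains on the lower side were beta-oxidation, fatty acid synthesis, succinylation enzymes and the unfolded protein response. Over the alternatives the adjusted p ranged from 9.86e-06 to 0.822 for complex I, 9.03e-06 to 0.822 for complexes II to V, 0.000609 to 0.975 for glycolysis and 0.00602 to 0.741 for epithelial genes. Of 24 uncalled lists 17 stayed uncalled throughout. Protein-coding genes by the file's own annotation and counts rebuilt from FPKM were not run, since the table gives no gene type and holds counts. With the depths, the variation between libraries and the 3 libraries per group of these data, 40% of simulated 1.5-fold changes were recovered. Whether these limit it or the small number of genes changed in the simulation was not tested.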

Other observations

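Chosen only after the result was seen were the 3 tests on RPPH1, the graded response, the residual change by number of sites and the reordered words of the 3' UTR site, the length trend among control libraries, and the test of Gene Ontology terms.

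Among 1162 Gene Ontology terms, camera with the preset correlation called 26 lower and 4 higher, and 0 terms with an estimated correlation. For cholesterol biosynthesis the unadjusted camera p was 3.25e-13 with the preset and 0.0039 with the estimated correlation. For the fixed lists the estimated version was stricter even at a correlation near the preset. Its 0 calls therefore do not show that no term stood apart. Beside sterol and translation terms, triglyceride metabolism (12 genes, median log2 change -0.59, adjusted p = 0.00478) and neutrophil chemotaxis (12 genes, median -0.43, adjusted p = 0.006) were lower. Microtubule-based movement was higher, with 15 of 46 genes higher and 2 lower (median 0.27, adjusted p = 0.0335), but not with the length and GC trends removed (median 0.18, adjusted p = 0.132). None of the 4 terms called higher passed with those trends removed (camera adjusted p from 0.113 to 0.579).

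The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3509 changed genes, 1762 higher and 1747 lower, and the highest of the others gave 0; for each of these counts 1 split, the real one, gave as many. The real split called 10 lists and the highest other 9, so 1 split gave as many; that other split set control replicates 1 and 3 with shRNA replicate 1 against the rest. The other splits called 1 to 9 lists with 0 genes called. Each of them put libraries of both groups on both sides, so the group difference entered their residual spread and partly their contrast. Their counts are therefore not those of data without a group difference, and they do not show how many calls would be false.

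RPPH1 was 379-fold higher in the shRNA libraries relative to total counts. The values argue against wider capture of small RNAs, since 51 other small RNA genes had a median log2 change of 0.0887 (quartiles -0.34 and 1.07, highest 2.27). PARP2, read from the shared promoter region in the other direction, had a log2 change of -0.15. That argues against higher activity of the region in both directions, but cannot exclude higher activity towards RPPH1 alone. A candidate explanation is reads from a hairpin construct: the H1 promoter used in many such constructs is the promoter of this gene, and the counted model was longer than the annotated RNA by 305 bases, 278 of them upstream. The labels do not name the vector or its promoter, and neither the reads nor a control with an empty construct were available. A rise of the endogenous RNA after CPT1A loss stays open and untested.

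Either of the 3' UTR words ATGTCCA (score -16.77) and TGTCCAA (score -14.22) was in 23.4% of searched lower genes and 15.2% of uncalled genes, with scores beyond the largest score of 5.38 in 200 permutations. The tables argue against base composition: the lowest score of the same bases in another order was -8.14, just short of the bound set at 0.5 of the top score, for a word (GTCCAAT) that shares 5 bases in a row with ATGTCCA and 6 with TGTCCAA, and -3.39 among words sharing no 4-base run. The hairpin may have acted as a small RNA on matching 3' UTRs. The median residual change was -0.236 with the 8-base site against 0.058 with none, in genes whose residuals also picked the site. The log2 changes themselves had medians of 0.039 with the 6-base site, -0.006 with TGTCCAA, -0.038 with ATGTCCA and -0.129 with the 8-base site. They fell in order across these site classes, but the genes with no site, at -0.009, lay below the 6-base class. The planned comparison of fold changes did not decide: the median was -0.033 with 2 or more sites and -0.04 with 1 (difference 0.007, 95% bootstrap interval -0.062 to 0.073), whereas the residuals differed by -0.083 (-0.14 to -0.043). Direct action on such sites would not account for cholesterol synthesis, where only 2 of 23 genes held one and the median stayed at -0.756 without them. An effect through a regulator of these genes was not tested. Without genes that hold a site, 8 of the 10 called lists kept their camera calls. Glycolysis and epithelial genes lost theirs (camera adjusted p = 0.0772 for both), and the unfolded protein response list gained one (camera adjusted p = 0.0315). The hairpin's sequence is not given, the tag sh2 of the deposited columns is not explained, and no other hairpin is labelled, so a regulator of the cell with the same site stays open.

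Longer genes were higher in the shRNA libraries, at a Spearman rho of 0.25 across genes. Whether this belongs to the knockdown or to the libraries cannot be told apart: the rank correlation with length ranged over 0.386 among the control libraries and differed by 0.387 between the groups. The trend was not the whole of the lower ribosomal protein genes, whose median stayed at -0.318 with the length and GC trends removed, nor of cholesterol synthesis, at -0.823. Complex I and complexes II to V lost their calls under the same correction, their medians moving from -0.25 and -0.25 to -0.14 and -0.17, so for them the trend may be part of the cause. A response of long genes to CPT1A loss was not tested.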
